A study of Mus musculus with 112 samples.

How the data were processed

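The series holds 112 Illumina bead arrays of mouse RNA. Per the labels, EpiSC at passages 10 to 20 were lifted with collagenase from a fibroblast layer, total RNA was extracted with RNeasy columns, and 230 ng of total RNA was labelled with the TotalPrep kit. The EpiSC9 cultures are labelled as passage 24. RNA of single epiblasts (E5.5 to E8.25) and of 4 EpiSC lines was first amplified with MessageAmp II. The authors summarised beads with BeadStudio, whose version is not given in the sources used here, nor are the array type and the genome build. The deposited table of raw values gives for each probe an intensity on a linear scale without background subtraction and a detection p-value against the negative control beads of its own array. A table of values processed by the authors, on a log2 scale with near-equal distributions over arrays, holds 31646 of the 45281 probes. Its medians lie between 6.87 and 6.94; the method behind it is not stated, and 3 of its columns matched another array best. It was used only as an alternative.

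The intensities were background-corrected with the detection p-values, quantile normalized and put on the log2 scale by the steps of limma's neqc (limma 3.58.1, R 4.3.3, R package data.table, version 1.17.8), with 16 added before the log and all 112 arrays normalized together. Probe names were matched to current symbols: of 28888 gene names, 15539 matched a symbol, 4392 a synonym and 8957 kept the name in the file. Where a gene had more than 1 probe (9740 genes), the probe with the highest mean over all arrays stood for it. A gene was tested when its detection p was under 0.01 on at least 3 arrays of the comparison.

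Groups came from the labels. The unit was the line: cultures were averaged to lines, and sublines with their line, for the comparisons of EpiSC with ESC, iPSC, MEF and EpiSC9 and for the stage of origin. Cultures were the unit for differences between lines, sublines and amplification, and single embryos with 4 line means for the epiblasts, joined into early (4), streak (6) and bud (7) periods. ESC, MEF and EpiSC9 are 1 line or cell type each, so their spread is that of the other groups. Tests were limma's moderated tests (lmFit, eBayes with trend), 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a limit of 0.05. ± gives the standard error of a log2 fold change unless SD is stated. Correlations and distances were tested with 100000 permutations, or all orders where these were few. When no array of the dimmer group detected the probe of a gene, only a bound is given: each array of the dimmer group is set to the lowest value among its own detected probes, or to the gene's value where that is higher, and the mean of the brighter group is divided by their mean (at least N-fold). The same bound is given where most of these arrays did not detect it, a rule chosen after seeing the results. Where only some arrays of the dimmer group detected a gene, their number is stated in the report, and its fold rests in part on values near background.

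The groups, the tests, the other alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. The rule takes in each comparison of a pair of groups the 8 genes with the highest and the 8 with the lowest log2 fold change among those that passed and were detected on every array of the higher group, in each F test the 8 with the smallest p, and any member of the lists. The lists are naive pluripotency, core pluripotency, post-implantation epiblast, primitive streak, anterior streak with node and definitive endoderm, mesoderm, neuroectoderm, Hox, visceral endoderm, extraembryonic ectoderm and trophoblast, fibroblast, germ cell, imprinted, sex-linked, glycolysis and hypoxia, proliferation, immediate early and heat shock, epithelium, and targets of Nodal and Activin, FGF and ERK, Wnt and BMP. Each was tested with camera at a preset correlation of 0.01 and again with an estimated one.

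Array sets were found from 13482 probes not above background (detection p above 0.1 on all but at most 3 arrays). A clustering of the arrays on these probes was cut into 7 sets, a number that was chosen and not itself tested. ESC and iPSC shared a set that held no other arrays. The sets entered as blocks or by comparing arrays within a set; these alternatives and some that left out lines or embryos were chosen after seeing the data. The other alternatives were the deposited values, no background correction, separate normalization of amplified arrays, median scaling, every probe on its own, no filter and a stricter one (detection on a share of 0.25 of arrays), a 2-fold minimum, sublines left out, only the 2 groups compared, line as a random block of cultures, replicate blocks, passage number as a covariate, and leaving out each replicate. A gap test at the 95 percent level looked for single samples far from the rest in 6 groups of 4 to 7 samples. It made 141 tests, on the means of the gene lists, probes detected, similarity to amplified EpiSC and the score of stage genes. The array of EpiSC9 RNA from another laboratory was left out of all comparisons. Slides could not be used as a block, since the files name none.

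The tests were tried on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold. Every group was given the spread of the not amplified EpiSC lines and cultures. The percents may thus differ for epiblasts, amplified arrays, ESC, iPSC and MEF, whose own spread was not used. For the test between lines, the simulated lines did not differ otherwise. At 2-fold and 4-fold change the percent found was 40 and 82 for EpiSC against ESC, 83 and 96 against iPSC, 36 and 89 against MEF, 29 and 86 for iPSC against ESC, and 33 and 89 for EpiSC9. It was 57 and 93 for the stage of origin, 62 and 96 for late bud against cavity, 84 and 100 between lines, and for the sublines 93 and 100 (CAV2), 96 and 100 (CAV3), 92 and 100 (LMS2) and 93 and 100 (LB1). For the epiblasts it was 67 and 90 between periods, and 57 and 92, 67 and 95, and 69 and 94 for amplified EpiSC against early, streak and bud epiblasts; for amplification it was 100 and 100. False calls numbered 2 to 18 per comparison.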

Results

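RNA of mouse cell lines and embryos was measured on 112 Illumina bead arrays. EpiSC are pluripotent lines grown from the epiblast, the layer of the early embryo that gives rise to the body, after implantation. The labels give 65 arrays of 18 EpiSC lines of the R1-129 strain. Of these lines, 4 had a subline from the same embryo that was thawed at another time, which makes 22 lines and sublines. The embryos of origin were at the cavity (4 lines), prestreak (3 lines), late midstreak (6 lines), early bud (2 lines) and late bud (3 lines) stages. There were 3 arrays of EpiSC9, a line of the 129SvJ strain from elsewhere, and 1 array of EpiSC9 RNA supplied by another laboratory. Other cells gave 3 arrays of 1 embryonic stem cell (ESC) line, 9 arrays of 3 induced pluripotent (iPSC) lines and 2 arrays of embryonic fibroblasts (MEF). By the labels the ESC line was of the R1-129 strain, the iPSC lines of a C57BL6 by C3H hybrid and the MEF of the ARC/s strain. Amplified RNA was measured on 12 arrays of the EpiSC lines CAV2, PS5, LMS3 and LB2 and on 17 arrays of single epiblasts. These were cavity 2, prestreak 2, late midstreak 3, late streak 3, no bud 1, early bud 3 and late bud 3.

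Of 45281 probes, 37.2% ± 1.56 (SD, n = 65) were detected on the EpiSC arrays, 29.6% ± 3.06 (SD, n = 12) on those of amplified EpiSC and 25.6% ± 2.43 (SD, n = 17) on those of epiblasts. The detected percent was 35.6 in ESC (n = 3), 36.1 in iPSC (n = 9), 33.2 in MEF (n = 2) and 36.7 in EpiSC9 (n = 3). Median intensities lay between 91.9 and 166 on the EpiSC arrays and between 92.3 and 132 on the epiblast arrays. The number of arrays limits the precision of every value.

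Genes of the naive state, the pluripotency of the embryo before implantation, were far lower in EpiSC than in ESC. Dppa5a, an RNA-binding protein of pluripotent cells, was at least 458-fold lower (18 lines against 1, adjusted p = 1.61e-13, lower in 18 of 18 lines; detected on 24 of 65 EpiSC arrays). Where only some arrays of the dimmer group detected a gene, their number follows its value, and where most did not, only a bound is given. Dppa4 (at least 261-fold, on 6 of 65), the nuclear receptor Esrrb (at least 165-fold, on 15 of 65) and the ESC transcription factors Tfcp2l1 (log2 fold change -5.23 ± 0.48, on 61 of 65, SE) and Zfp42 (at least 24.9-fold, on 2 of 65) were lower too. Dppa5a (13.60 to 13.86) and Dppa4 (12.76 to 13.06) were also high in the amplified cavity and prestreak epiblasts, which are past implantation. Low values of these genes therefore do not by themselves mark the loss of the naive state. In the naive pluripotency list, 15 of 18 measured members were lower, 0 higher and 3 did not pass (16 adjusted over the list alone; camera adjusted p = 3.99e-22, adjusted p = 3.18e-05 with an estimated correlation). The members that did not pass were Nanog (-0.70 ± 0.44, adjusted p = 0.254), Klf4 (-1.89 ± 0.77, adjusted p = 0.0739) and Gbx2 (1.00 ± 0.82, adjusted p = 0.384). Nanog passed on the deposited values (adjusted p = 0.0467), and Klf4 in 2 of 15 alternatives.

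The core pluripotency factor Pou5f1 averaged 12.09 in EpiSC and 13.04 in ESC on the log2 scale (adjusted p = 0.305), and Sox2 8.77 and 9.59 (adjusted p = 0.225). Utf1, a chromatin factor, was 17.8-fold lower (on 63 of 65) and L1td1 8.76-fold, among 3 lower members of 11 in the core pluripotency list (4 adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.764 with an estimated correlation). That call was lost in 3 of 12 alternatives (camera adjusted p = 0.0539 without the sublines, 0.0723 with only these groups compared and 0.0787 without iPSC line 3). Germ cell genes were lower in 4 of 8 cases (4 adjusted over the list alone), among them Tfap2c (-4.72 ± 0.91) and the translational regulator Nanos3 (at least 1.85-fold, on 1 of 65), with camera adjusted p = 0.000637 and adjusted p = 0.00584 with an estimated correlation. Their camera value was 0.189 under a stricter filter on detection. Of 11 epithelium genes, 6 were lower, such as the adhesion molecule Cdh1 (-2.51 ± 0.58), the tight junction gene Cldn4 (-5.94 ± 0.73, on 50 of 65) and Grhl2 (-3.81 ± 0.68, on 36 of 65). The same 6 passed adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.552 with an estimated correlation).

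Imprinted genes were mostly higher in EpiSC: 8 of 14 rose and 1 fell (8 and 2 adjusted over the list alone). H19 (3.30 ± 0.68), Meg3 (3.66 ± 0.54), Dlk1 (3.41 ± 0.63) and Nnat (at least 20.6-fold, on 1 of 3) were among them (camera adjusted p = 0.00662, adjusted p = 0.0630 with an estimated correlation). In the neuroectoderm list 5 of 11 members were higher (5 adjusted over the list alone), including the midbrain homeobox gene En1 (3.93 ± 0.82; camera adjusted p = 0.00662, adjusted p = 0.561 with an estimated correlation). In the anterior streak, node and definitive endoderm list 5 of 14 were higher (5 adjusted over the list alone), including the node signal Shh, at least 29.2-fold higher, since no ESC array detected it (camera adjusted p = 0.0212, adjusted p = 0.764 with an estimated correlation). The first of these was 0.0507 on the deposited values. Of 14 primitive streak genes, 3 rose, among them T (3.05 ± 0.86), the transcription factor of nascent mesoderm, and Fgf8 (3.06 ± 0.91), while 2 fell, among them Fgf17 (-4.12 ± 0.91, on 58 of 65; camera adjusted p = 0.555). Fgf5, a marker of the epiblast after implantation, was 2.79 ± 0.97 (adjusted p = 0.0379), a call lost in 5 of 15 alternatives. Car14, a carbonic anhydrase, was 4.87 ± 0.47. The extraembryonic ectoderm and trophoblast list had 1 higher and 4 lower of 11 (1 and 5 adjusted over the list alone; camera adjusted p = 0.143). Among sex-linked genes 0 of 5 passed (0 adjusted over the list alone; camera adjusted p = 0.633).

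Over all 15032 genes tested, 3939 passed, 1950 higher and 1989 lower in EpiSC. The largest differences included Maged1, at least 170.4-fold higher, the homeobox gene Meis2, 48.4-fold, and Igfbp5 (5.15 ± 0.97) on the higher side. On the lower side were Dnmt3l (at least 356-fold, on 20 of 65), a cofactor of DNA methylation, and Rhox5 (-7.68 ± 0.37, on 33 of 65). The fibroblast genes Lum (at least 14.8-fold, on 1 of 3) and Dcn (4.09 ± 1.12), which encode matrix proteoglycans, were higher in the EpiSC arrays, 3 of 17 in that list (3 adjusted over the list alone; camera adjusted p = 0.633). The labels state that EpiSC were grown on a layer of fibroblasts, and its part in these values was not tested. The ESC and iPSC arrays formed an array set of their own in the background probes. With the set as a random block 3241 genes passed. No EpiSC array lay in the set of ESC, so set and cell type cannot be told apart by this block.

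Against the iPSC lines, pluripotent lines made from tail fibroblasts of a C57BL6 by C3H hybrid, EpiSC again had lower naive genes. Dppa5a (at least 427-fold, on 24 of 65, 18 lines against 3, lower in 18 of 18 lines), Dppa4 (at least 247-fold, on 6 of 65), Esrrb (at least 215-fold, on 15 of 65) and Zfp42 (at least 88.3-fold, on 2 of 65) were lower. So was Nanog (-1.17 ± 0.27, SE, adjusted p = 0.00122). Of 18 naive genes 17 were lower (17 adjusted over the list alone; camera adjusted p = 1.92e-22, adjusted p = 2.88e-05 with an estimated correlation). All 8 germ cell genes were lower (8 adjusted over the list alone), for example Tfap2c (-3.47 ± 0.55) and Dazl, a regulator of germ cell translation, at least 8.35-fold (camera adjusted p = 5.43e-05, adjusted p = 0.00162 with an estimated correlation). Of 14 imprinted genes 9 were higher and 2 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00268, adjusted p = 0.0420 with an estimated correlation), such as Dlk1 (3.06 ± 0.38) and the cell cycle inhibitor Cdkn1c (2.95 ± 0.32).

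Visceral endoderm genes were lower in EpiSC in 11 of 18 cases (11 adjusted over the list alone), with Amn at -2.88 ± 0.30, on 61 of 65 and the transport protein Ttr at least 3.04-fold lower (camera adjusted p = 0.000276, adjusted p = 0.417 with an estimated correlation). The Ttr difference came from iPSC lines 1 and 2 (mean 7.99), since no array labelled iPSC line 3 detected it (mean 4.47). Neuroectoderm genes were higher in 7 of 11 cases (8 adjusted over the list alone), with En1 at 3.21 ± 0.50 (camera adjusted p = 0.00239, adjusted p = 0.417 with an estimated correlation). Hox genes were higher in 4 of 15 cases (3 adjusted over the list alone), a shift that camera called at adjusted p = 0.0463 (adjusted p = 0.754 with an estimated correlation). That call was lost in 9 of 12 alternatives, with camera adjusted p up to 0.102. T (2.64 ± 0.52, on 7 of 9) and Fgf8 (2.54 ± 0.55, on 7 of 9) were higher here as well. In all, 6367 genes passed, 3285 higher and 3082 lower. As a random block, the array set left 4543. Since iPSC and EpiSC shared no set, this block does not part set from cell type. Their labelled strains differ as well, so strain and cell type cannot be told apart either.

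Compared with fibroblasts, genes of pluripotency and of dividing cells were higher in EpiSC. Pou5f1 was at least 92.6-fold higher (adjusted p = 4.45e-09, higher in 18 of 18 lines) and Nanog at least 39.1-fold. No MEF array detected either. Of 11 core pluripotency genes 10 were higher (11 adjusted over the list alone; camera adjusted p = 3.69e-07, adjusted p = 0.140 with an estimated correlation). In the list of the epiblast after implantation 12 of 16 were higher (13 adjusted over the list alone), with the DNA methyltransferase Dnmt3b at 6.72 ± 0.62 and Fgf5 at 3.80 ± 0.97, on 1 of 2 (SE, 18 lines against 1; camera adjusted p = 3.56e-06, adjusted p = 0.112 with an estimated correlation). Nodal and Activin targets were higher in 8 of 9 cases (8 adjusted over the list alone; camera adjusted p = 2.99e-05, adjusted p = 0.0395 with an estimated correlation), with the Nodal antagonist Lefty1 at least 133-fold higher. Of 15 proliferation genes 13 were higher (14 adjusted over the list alone), such as Mki67 (4.17 ± 0.37) and the cyclin Ccnb1 (3.99 ± 0.18; camera adjusted p = 7.35e-11, adjusted p = 0.0395 with an estimated correlation).

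Of 17 fibroblast genes 16 were lower in EpiSC (16 adjusted over the list alone; camera adjusted p = 3.69e-07, adjusted p = 0.294 with an estimated correlation), among them the collagens Col1a1 (-3.70 ± 0.81) and Col3a1 (-3.44 ± 0.83, on 63 of 65). The matrix gene Dcn stood at 11.60 in EpiSC and 13.70 in MEF (adjusted p = 0.136). It passed as lower in EpiSC in 4 of 14 alternatives, such as among the arrays of the set that held MEF (-1.37, adjusted p = 0.0107). The labels state that the EpiSC were grown on a layer of fibroblasts. Of 13 glycolysis and hypoxia genes 7 were higher (7 adjusted over the list alone), with the glucose transporter Slc2a3 at 5.63 ± 0.40 (camera adjusted p = 0.0212, adjusted p = 0.676 with an estimated correlation, and 0.052 under median scaling). In all 6511 genes passed, 3363 higher and 3148 lower. With the array set as a block 5996 passed, and 5821 among the arrays of the set that held MEF, where the fibroblast list shifted by -2.73. The MEF were of another strain than the EpiSC, so this comparison does not separate strain from cell type.

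Between iPSC and ESC no gene passed in limma: 0 of 15032, with 1165 at an unadjusted p under 0.05 and a smallest adjusted p of 0.160. Genes of the visceral endoderm list had higher averages in iPSC, such as Ttr (6.82 against 4.48, adjusted p = 0.398) and the endoderm factor Gata6 (7.34 against 4.83, adjusted p = 0.587; 3 lines against 1). The list as a whole was called by camera at adjusted p = 1.38e-07 (adjusted p = 0.499 with an estimated correlation), with 0 of 18 members past the test and 4 higher adjusted over the list alone. Epithelium genes averaged lower (-0.76; camera adjusted p = 0.0352, adjusted p = 0.978 with an estimated correlation; 0 of 11 passed, 0 adjusted over the list alone). That call was lost in 6 of 15 alternatives, with camera adjusted p up to 0.193. The arrays labelled iPSC line 3 correlated with ESC at r = 0.995 to 0.996 across genes, which are not independent replicates, and those of lines 1 and 2 at 0.925 to 0.947. Without iPSC line 3, 1354 genes passed, with Dppa3 lower (adjusted p = 1.13e-17) and Zfp42 (adjusted p = 5.35e-11), Ttr (adjusted p = 4.62e-13) and Gata6 (adjusted p = 0.0182) higher. Ttr passed in 4 of 17 alternatives and Gata6 in 1 of 18. The array set as a random block gave 143 genes, and cultures as the unit with the line as a random block gave 250. The labelled strains of iPSC and ESC differ, so strain and cell type cannot be told apart in these counts.

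**Figure D1:**
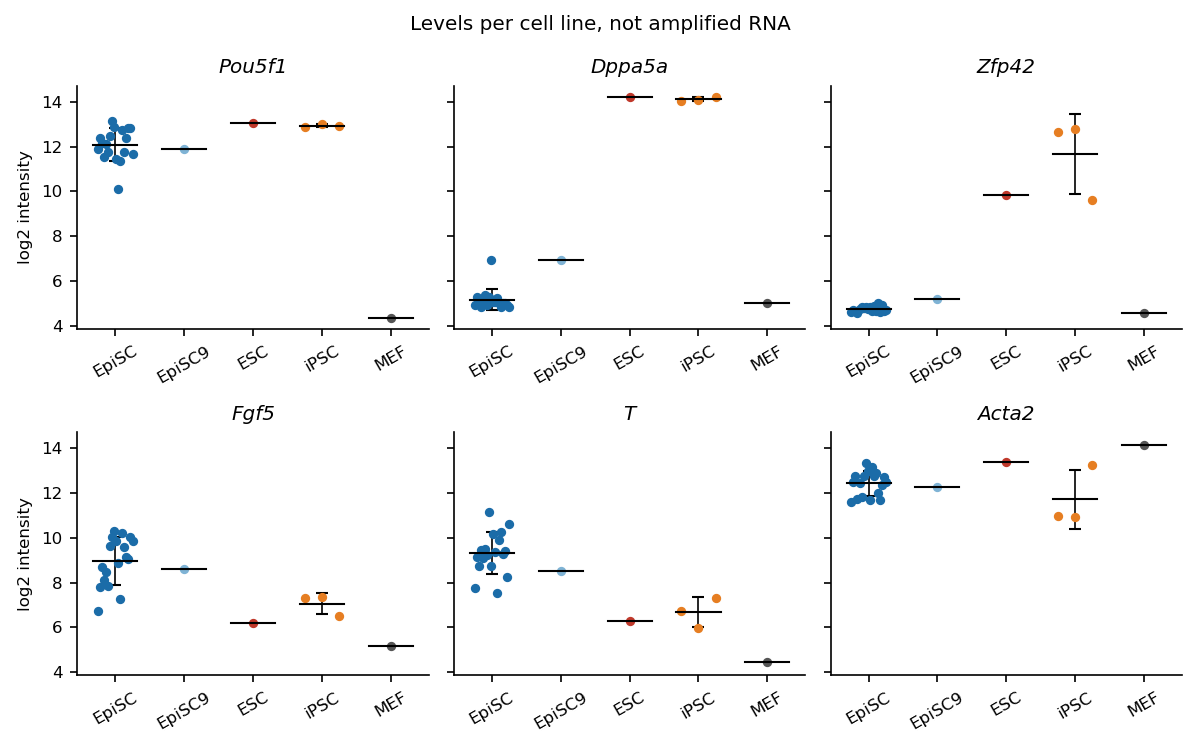
Log2 intensity of 6 genes in each cell line, 1 point per line, with bars for the group mean and whiskers for the SD. Dppa5a and Zfp42 lay low in all EpiSC lines and high in ESC and iPSC, while Pou5f1 averaged 12.09 in EpiSC and 13.04 in ESC.

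EpiSC9, from another 129 substrain, differed from the R1-129 lines in 254 genes, 204 higher and 50 lower. The number was 120 in the shared array set alone, 611 without EpiSC9 culture 1 and 949 without the filter on detection, and on simulated data the test found 33 percent of 2-fold changes. Nr5a2, a nuclear receptor of early embryonic cells, was at least 18.5-fold higher (1 line against 18, adjusted p = 6.93e-09; detected on 9 of 65 R1-129 arrays), and so was the somite gene Meox1 (at least 14.7-fold, on 32 of 65). Nckap1l (5.25 ± 0.46, on 48 of 65; SE) and the endothelial genes Cldn5 (at least 11.5-fold, on 22 of 65) and Emcn (at least 6.21-fold, on 21 of 65) were higher. Picalm (-3.76 ± 0.39, on 2 of 3) and Arhgap12 (-2.25 ± 0.24) were lower. In the epithelium list 2 of 11 were higher (6 adjusted over the list alone; camera adjusted p = 2.89e-06, adjusted p = 0.502 with an estimated correlation). In the mesoderm list 2 of 11 were higher, Meox1 and Foxc2 (at least 2.32-fold, on 12 of 65), and 3 adjusted over the list alone (camera adjusted p = 0.00447, adjusted p = 0.502 with an estimated correlation, and 0.0993 without the filter). The glycolysis and hypoxia list averaged 0.66 higher with 0 of 13 past the test (0 adjusted over the list alone; camera adjusted p = 0.00083, adjusted p = 0.673 with an estimated correlation). T (-0.80 ± 0.86, adjusted p = 0.761) and Pou5f1 (-0.21 ± 0.66, adjusted p = 0.935) did not pass.

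With the array set as a block 289 genes passed. In the shared set alone the epithelium list shifted by 1.87 and the mesoderm list by 1.25. Strain and line cannot be separated, since EpiSC9 was the only line of its strain.

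The series asks whether EpiSC from embryos of different stages are equivalent. Across the 5 stages of origin 2 of 14339 genes passed limma's F test, with 1180 at an unadjusted p under 0.05. They were the mitochondrial gene MTDNA_ND6 (adjusted p = 0.000222, stage means from 4.58 to 5.89) and Dipk1c (adjusted p = 0.0114, stage means from 5.25 to 6.59). With EB1a and EB1b as 1 line Dipk1c was at adjusted p = 0.454, and 1 gene passed. Tekt1, above the limit here, passed in 5 of 23 alternatives, Ubxn10 in 2 of 21 and 1700003E16Rik in 2 of 22. Without the filter 20 genes passed and without sublines 10. With the line number as a replicate block 0 passed (MTDNA_ND6 at adjusted p = 0.0561, Dipk1c at 0.0697). The test used 18 line means. In it 0 genes passed without line EB1b, 1 of only 2 early bud lines, and 1 without EB1a. Among the genes fixed in lists, Noto, a gene of the node, had stage means from 4.65 to 5.42 (adjusted p = 0.15), and Sfrp2, a Wnt inhibitor, from 7.84 to 9.47 (adjusted p = 0.242). Between late bud and cavity origin 0 genes passed in limma, with 803 at an unadjusted p under 0.05. T was 0.64 ± 0.68 (SE, 3 lines against 4, adjusted p = 0.892) and Pou5f1 0.45 ± 0.56 (adjusted p = 0.906). With the array set as a block 5 genes passed the F test, while MTDNA_ND6 and Dipk1c were each at an adjusted p of 0.138. Between late bud and cavity it was 0 again.

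Whole profiles were no farther apart between stages of origin than within them. The mean distance, 1 minus r over genes, was 0.0238 between lines of different stages (125 pairs) and 0.0288 between lines of the same stage (28 pairs), a difference of -0.00503 (1-sided permutation p = 0.955). It was -0.00352 with the means of the array sets removed. Genes that differed with stage in the embryo, 1251 higher and 1349 lower at bud stages, were scored in each of the 18 lines. The score did not follow the stage of origin (Pearson r = -0.242, permutation p = 0.334; Spearman rho = -0.136, permutation p = 0.590; 2-sided). Pearson r was -0.236 to 0.0649 without the 2 lines farthest from the median stage and -0.278 with the array set means removed.

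Between individual lines, judged against the spread between cultures of the same line, the differences were wide. In limma's F test over the 22 lines and sublines 13320 of 14339 genes passed, and 12688 within array sets. The test does not separate a line from its thaw: the same fit called 4829 to 6428 genes between a line and its own subline. Shh ranged from 5.17 to 12.32 in line means and Nnat from 4.46 to 11.91. The sex-linked genes Xist, the RNA of the inactive X chromosome, and Eif2s3y, on the Y chromosome, ranged from 4.41 to 10.13 and from 4.31 to 10.15. All members passed in the lists of naive (12 of 12) and core pluripotency (11 of 11), primitive streak (13 of 13), neuroectoderm (11 of 11), Hox (15 of 15) and Nodal and Activin targets (9 of 9), the same counts adjusted over the list alone.

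A subline and its line share the embryo, but in all 4 pairs they differ in passage number and array set as well as thaw. The tests use the spread between cultures, not between thaws, so they do not measure how far a line moves between thaws. In the CAV2 subline immediate early genes, the first to respond to growth signals and stress, were lower. Fosb was 35.8-fold lower (-5.16 ± 0.30, SE, 3 cultures against 3, adjusted p = 9.47e-20, lower in 3 of 3 cultures), Fos -2.74 ± 0.27 and Junb -2.10 ± 0.18. Of 14 members 11 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 9.14e-09, adjusted p = 0.00371 with an estimated correlation). All 9 epithelium genes were lower (9 adjusted over the list alone), such as Cldn3 (-1.90 ± 0.20; camera adjusted p = 0.000138, adjusted p = 0.0613 with an estimated correlation). Primitive streak genes were higher in 7 of 13 cases (7 adjusted over the list alone), led by Wnt3a (mean 10.10 against 5.10) with Fgf8 (1.54 ± 0.30) behind it (camera adjusted p = 0.00402, adjusted p = 0.234 with an estimated correlation). The homeobox gene Msx3 (5.13 ± 0.31) and Tfap2b (3.87 ± 0.26) were higher as well. In all 6338 genes passed, 2930 higher and 3408 lower.

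In the CAV3 subline the immediate early genes were lower as well: 9 of 14, 0 higher (9 adjusted over the list alone; camera adjusted p = 2.42e-08, adjusted p = 0.00508 with an estimated correlation). Fosb was at -4.39 ± 0.30 and Junb at -3.01 ± 0.18 (SE, 3 cultures against 3). Nodal and Activin targets were lower in 8 of 9 cases (9 adjusted over the list alone), with Nodal itself at -2.61 ± 0.25 and its co-receptor Tdgf1 at -2.71 ± 0.27 (camera adjusted p = 1.04e-05, adjusted p = 0.0535 with an estimated correlation). Core pluripotency genes were lower in 9 of 11 cases and higher in 1 (the same adjusted over the list alone), with Pou5f1 at -1.71 ± 0.16 (camera adjusted p = 0.000224, adjusted p = 0.0535 with an estimated correlation). Genes of the epiblast after implantation were lower in 11 of 16 and higher in 1 (the same adjusted over the list alone), with Fgf5 at -2.69 ± 0.30 and Otx2 at -1.91 ± 0.21 (camera adjusted p = 8.09e-05, adjusted p = 0.0535 with an estimated correlation). Hox genes, which pattern the body axis, were higher in 12 of 15 cases (12 adjusted over the list alone), with Hoxb2 at 2.76 ± 0.25 (camera adjusted p = 8.09e-05, adjusted p = 0.109 with an estimated correlation). The neural gene Zic1 was at 2.18 ± 0.31. In all 6428 genes passed, 3235 higher and 3193 lower.

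In the LMS2 subline, genes of the streak and node were lower. In the list of the anterior streak, node and definitive endoderm 11 of 14 genes were lower (11 adjusted over the list alone; camera adjusted p = 6.9e-08, adjusted p = 0.0156 with an estimated correlation), including the organizer gene Gsc (-2.54 ± 0.32, SE, 3 cultures against 3), Shh (-2.35 ± 0.19), Foxa2 (-1.86 ± 0.20) and the endoderm factor Sox17, at least 3.61-fold. Primitive streak genes were lower in 8 of 13 cases (9 adjusted over the list alone), with T at -3.08 ± 0.30 and Lhx1 lower by at least 13.9-fold (on 1 of 3; camera adjusted p = 4.95e-05, adjusted p = 0.163 with an estimated correlation). Fibroblast genes were higher in 15 of 17 cases (16 adjusted over the list alone), such as Col5a1 (1.37 ± 0.18; camera adjusted p = 1.29e-07, adjusted p = 0.163 with an estimated correlation). The surface receptor Cd44 (2.80 ± 0.20) and the hormone Stc1 (2.72 ± 0.21) moved with them. Per the labels EpiSC were grown on a layer of fibroblasts, and its part in these values was not tested. In all 5677 genes passed, 2663 higher and 3014 lower.

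In the LB1 subline targets of FGF and ERK signalling were lower: 6 of 7 (6 adjusted over the list alone; camera adjusted p = 7.52e-06, adjusted p = 0.00425 with an estimated correlation). Phlda1 was at -3.37 ± 0.22 and the phosphatases Dusp4 and Dusp6 at -2.25 ± 0.21 and -1.29 ± 0.12 (SE, 3 cultures against 3). Naive genes were lower in 7 of 12 cases (7 adjusted over the list alone), with Klf2 at -2.80 ± 0.19 and Klf4 at -1.36 ± 0.25 (camera adjusted p = 0.000815, adjusted p = 0.00313 with an estimated correlation). Nodal (-1.81 ± 0.25) and the Wnt target Sp5 (-3.10 ± 0.32) were lower too, and the acute-phase gene Serpina3n (2.78 ± 0.29) was higher. In all 4829 genes passed, 2102 higher and 2727 lower. Each line and its subline lay in different array sets, and a random block does not fully separate the set from the subline. With the set as a random block 5205 genes passed for CAV2, 5856 for CAV3, 4395 for LMS2 and 3652 for LB1.

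**Figure D2:**
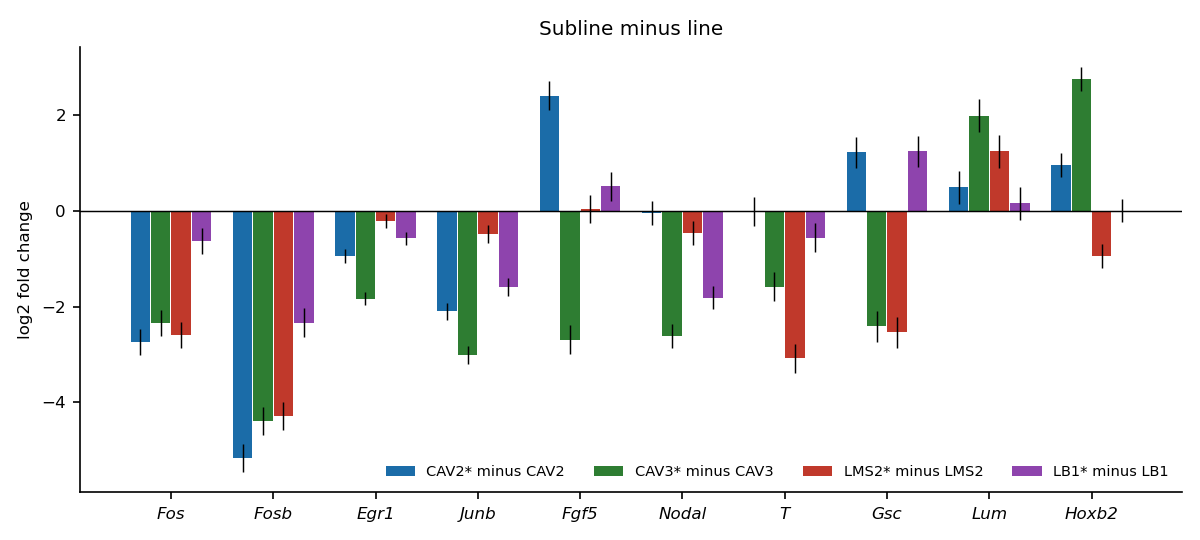
Log2 fold change (subline minus line) with SE for 10 genes in the 4 pairs, 3 cultures against 3 in each. Fosb lay below 0 in all pairs, while T fell by 3.08 in the LMS2 subline.

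In the embryo itself, epiblasts of the bud stages (7) were compared with those of the cavity and prestreak stages (4). Several patterning genes rose. The Iroquois gene Irx5 was at least 31.6-fold higher (adjusted p = 7.12e-12, higher in 7 of 7 embryos), the Wnt ligand Wnt3a at least 13.6-fold and T at least 4.87-fold, all undetected in the early group. Irx3 (at least 39.1-fold, on 1 of 4) and the caudal gene Cdx2 (at least 22.9-fold, on 1 of 4) rose too. Of 8 neuroectoderm genes 3 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.0215, adjusted p = 0.249 with an estimated correlation). Of 13 primitive streak genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00811, adjusted p = 0.435 with an estimated correlation). Wnt targets rose in 6 of 8 cases (6 adjusted over the list alone), such as Sp5, at least 23.8-fold (camera adjusted p = 0.00199, adjusted p = 0.0878 with an estimated correlation). BMP targets rose in 3 of 6 cases (4 adjusted over the list alone), with Id2 at 2.43 ± 0.41, on 3 of 4 (SE; camera adjusted p = 0.0303, adjusted p = 0.406 with an estimated correlation), a call lost in 3 of 16 alternatives. Imprinted genes rose in 7 of 13 cases (8 adjusted over the list alone), such as Peg3 (2.69 ± 0.26) and the growth factor Igf2 (2.19 ± 0.29; camera adjusted p = 0.00513, adjusted p = 0.0847 with an estimated correlation).

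Pluripotency genes went both ways with stage. Among 12 naive members 5 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.983), with Dppa4 down at least 68.7-fold and Dppa5a by 18.1-fold (-4.18 ± 0.27). Pou5f1 fell (-3.31 ± 0.53, on 4 of 7), as did Sox2, at least 2.27-fold. Of 11 core pluripotency genes 5 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.0374, adjusted p = 0.406 with an estimated correlation), a call lost in 4 of 16 alternatives. Nodal and Activin targets fell in 7 of 9 cases (7 adjusted over the list alone), with Nodal at -3.99 ± 0.34, on 6 of 7 and Gdf3 lower by at least 9.13-fold (on 3 of 7; camera adjusted p = 4.64e-05, adjusted p = 0.0547 with an estimated correlation). Genes of the epiblast after implantation fell in 8 of 14 cases (9 adjusted over the list alone), with Fgf5 at -2.43 ± 0.29 and Pou3f1 at -2.32 ± 0.31 (camera adjusted p = 0.00146, adjusted p = 0.0847 with an estimated correlation). In all 4089 of 12019 genes passed, 2157 higher and 1932 lower. Every bud epiblast array detected fewer probes (9624 to 11431) than every early one (11512 to 12683), so the comparison does not separate stage from the yield of RNA or amplification. With the array set as a block 3674 passed, and 4720 within the set that held cavity, prestreak and late bud embryos, where Nodal and Activin targets shifted by -2.77, Wnt targets by 2.48 and BMP targets by 1.52, the last with camera adjusted p = 0.0879. Ttr, a transcript of the visceral endoderm that surrounds the epiblast, was detected in cavity embryo 2 (7.45), prestreak embryo 2 (6.70), late midstreak embryo 2 (9.42) and late streak embryo 3 (7.47). Without these embryos 1706 genes passed.

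The amplified EpiSC arrays were set against the epiblasts to ask which stage the lines resemble. Against the early epiblasts, EpiSC had far more Acta2, smooth muscle actin, at least 132-fold (adjusted p = 1.81e-10, higher in 4 of 4 lines), the Nodal antagonist Lefty1 (6.74 ± 0.41, on 2 of 4, SE, 4 lines against 4 embryos) and the growth factor gene Igf2 (4.86 ± 0.32). They had far less Dppa5a (at least 215-fold, on 1 of 12), Dppa4 (-7.10 ± 0.46, on 7 of 12) and Rab25 (at least 30.5-fold, on 3 of 12), a trafficking protein of epithelia. Of 15 fibroblast genes 14 were higher (15 adjusted over the list alone; camera adjusted p = 3.12e-10, adjusted p = 0.00994 with an estimated correlation), such as Dcn (3.20 ± 0.64) and Col5a1 (3.56 ± 0.34). Per the labels EpiSC were grown on a layer of fibroblasts, and the not amplified MEF arrays had Acta2 at 14.17. The fibroblast genes, here and against later epiblasts, therefore do not separate EpiSC from that layer. Immediate early genes were higher in 10 of 13 cases and lower in 1 (the same adjusted over the list alone), with Egr1 at 5.32 ± 0.70 (camera adjusted p = 0.00036, adjusted p = 0.275 with an estimated correlation). Neuroectoderm genes were higher in 7 of 8 cases (7 adjusted over the list alone), with Irx3 up at least 25.4-fold (on 1 of 4; camera adjusted p = 9.26e-05, adjusted p = 0.0305 with an estimated correlation). Hox genes were higher in 7 of 11 (9 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.267 with an estimated correlation). Genes of the epiblast after implantation were lower in 9 of 14 cases (9 adjusted over the list alone), with Otx2 at -2.26 ± 0.29 (camera adjusted p = 0.000191, adjusted p = 0.0347 with an estimated correlation). Pou5f1 was at -1.41 ± 0.59 (adjusted p = 0.0676), but passed as lower in 4 of 19 alternatives, at -2.27 without the lines labelled PS5 and LB2 (adjusted p = 0.0123). In all 4424 genes passed, 2625 higher and 1799 lower. The amplified CAV2, PS5 and LB2 arrays detected more probes (13548 to 14804) than any epiblast array (9624 to 13151). Those of LMS3 lay within the epiblast range (11137 to 11227). The comparisons with early, streak and bud epiblasts therefore do not separate cell type from the yield of RNA or amplification. The number was 3462 with the array set as a block, where the fibroblast list shifted by 2.58, and 2495 without the 4 embryos with Ttr.

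Against the streak epiblasts (6), Acta2, at least 148-fold, and Lefty1, at least 96.2-fold, were higher in EpiSC (4 lines). Streak genes were lower: 5 of 13 (5 adjusted over the list alone; camera adjusted p = 0.00170, adjusted p = 0.268 with an estimated correlation), including Mesp1, an early mesoderm factor, at least 6.98-fold, Evx1 (at least 12.2-fold, on 4 of 12) and Eomes (-2.82 ± 0.47, on 9 of 12; SE). T was at -0.76 ± 0.74 (adjusted p = 0.467). Cdx2 (at least 12.8-fold, on 4 of 12) was lower too. Nodal and Activin targets were higher in 4 of 9 cases (4 adjusted over the list alone), with Gdf3 at 3.10 ± 0.43, on 4 of 6 (camera adjusted p = 0.000224, adjusted p = 0.0512 with an estimated correlation). Of 15 fibroblast genes 14 were higher (14 adjusted over the list alone; camera adjusted p = 3.38e-12, adjusted p = 0.00420 with an estimated correlation). In all 3825 genes passed, 2245 higher and 1580 lower. The number was 4016 with the array set as a block and 2270 within the set that held late streak embryos, where the streak list shifted by -1.73 and the fibroblast list by 2.58.

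Against the bud epiblasts (7), EpiSC were higher in Nodal and its targets. Nodal was 15.1-fold higher (3.91 ± 0.34, on 6 of 7, SE, 4 lines, adjusted p = 8.84e-09) and Gdf3 at least 6.20-fold (on 3 of 7). Pluripotency genes went both ways, with 4 of 11 core members higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.802). Sox2 was at least 2.45-fold higher and the naive gene Dppa5a at least 11.8-fold lower (on 1 of 12). Pou5f1 was at 1.90 ± 0.53, on 4 of 7 (adjusted p = 0.00599), but 0.223 without the lines labelled PS5 and LB2. Nodal and Activin targets were higher in 7 of 9 cases (8 adjusted over the list alone; camera adjusted p = 9.12e-06, adjusted p = 0.0202 with an estimated correlation). Cdx2 (at least 31.3-fold, on 4 of 12), Wnt3a (-4.36 ± 0.66, on 6 of 12), Nkx1-2 (-3.91 ± 0.55, on 6 of 12) and Evx1 (at least 6.83-fold, on 4 of 12) were lower. In all 8 of 13 primitive streak genes were lower (8 adjusted over the list alone; camera adjusted p = 0.00213, adjusted p = 0.269 with an estimated correlation). Wnt targets such as Axin2 (-1.64 ± 0.35) were lower in 5 of 8 cases (5 adjusted over the list alone; camera adjusted p = 0.00449, adjusted p = 0.188 with an estimated correlation). BMP targets such as Msx1 (at least 2.71-fold, on 1 of 12) and Id2 (-2.14 ± 0.41) were lower in 5 of 6 (5 adjusted over the list alone; camera adjusted p = 0.00213, adjusted p = 0.191 with an estimated correlation). Fibroblast genes were higher in 13 of 15 cases (13 adjusted over the list alone; camera adjusted p = 4.62e-08, adjusted p = 0.0202 with an estimated correlation). In all 5330 genes passed, 2815 higher and 2515 lower. The number was 5336 with the array set as a block and 3403 within the set that held no bud and early bud embryos, where the Nodal list shifted by 2.88, the Wnt list by -1.35 and the BMP list by -1.74.

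**Figure D3:**
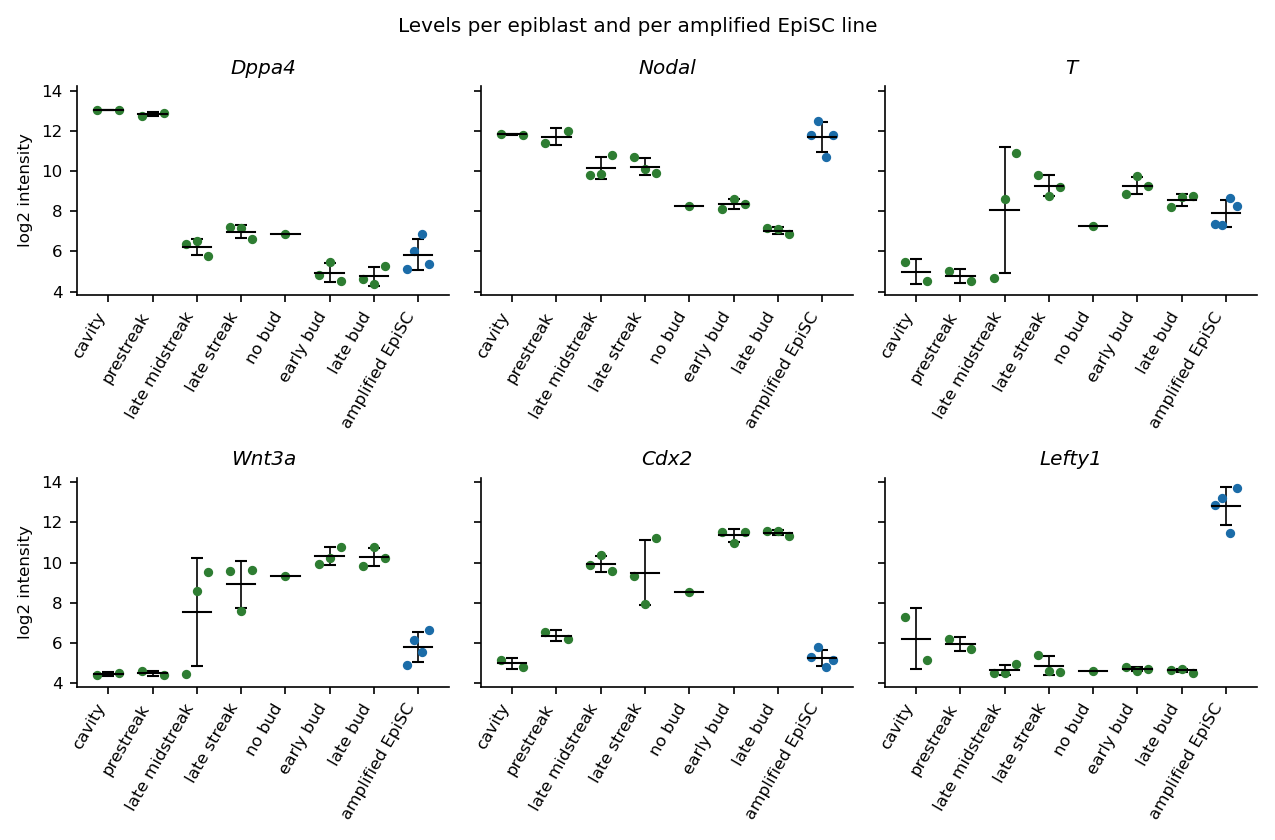
Log2 intensity of 6 genes in each epiblast by stage and in each amplified EpiSC line. Dppa4 lay high in the early epiblasts (mean 12.94) and low in the bud epiblasts (mean 5.14), and Nodal averaged 11.70 in the EpiSC lines.

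The mean r of each epiblast with the 4 amplified EpiSC lines, after centring each gene, averaged -0.403 at the cavity, -0.354 at the late streak, -0.262 at the no bud (1 embryo), -0.430 at the early bud and -0.387 at the late bud stage. Each gene was centred midway between the mean of the epiblasts and that of the EpiSC lines. This puts them on opposite sides, so the negative sign of r follows from the centring and does not mean opposite profiles. Without centring the ranks differed, with the no bud embryo lowest (0.816) and the late streak stage highest (0.857). With all 17 embryos and 4 lines no relation to the order of stages passed (Spearman rho = 0.0892, permutation p = 0.732; Pearson r = 0.0465, permutation p = 0.865; 2-sided). Pearson r was -0.0853 to 0.102 without the 2 embryos farthest from the median stage, with the r of each embryo kept from the full data. With fewer samples the relation passed in either direction. In those fits, except the one within an array set, genes were centred again on the samples that remained. This shifts the r of every embryo, so these values do not show the effect of the left-out samples alone. By lines, rho was 0.646 without the line labelled PS5 (p = 0.00648), 0.554 without LB2 (p = 0.0229), 0.742 without both (p = 0.00091) and -0.368 without LMS3 (p = 0.146). By embryos, it was 0.798 without 2 embryos described as cultured (p = 0.00051), -0.596 without the 4 embryos with Ttr (p = 0.0341) and -0.694 within the array set of the late streak, no bud and early bud embryos (exact p = 0.129). A line was no nearer to epiblasts of its own stage of origin than to those of other stages (mean r -0.0782 after centring, 1-sided exact permutation p = 0.75, 24 orders of 4 lines).

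To measure the effect of amplification itself, amplified and not amplified arrays of the same 4 lines were compared. The ribosomal protein gene Rpl7a was at least 73.5-fold lower after amplification (adjusted p = 4.91e-28, lower in 12 of 12 cultures), the actin-binding Tmsb10 187-fold lower (-7.54 ± 0.20, on 7 of 12, SE, 12 arrays against 12) and the splicing factor Snrpd1 55.8-fold (-5.80 ± 0.28, on 9 of 12). Thoc3 (4.02 ± 0.14) and Cntn2 (at least 20.5-fold, on 3 of 12) were higher. Pou5f1 fell by 2.50 ± 0.18, Top2a, a topoisomerase of dividing cells, by 2.93 ± 0.35 (on 10 of 12), and Col1a1 by 2.82 ± 0.14 (on 8 of 12). In all 10330 of 13139 genes passed, 5833 higher and 4497 lower. As a random block, the array set left 8449. All amplified EpiSC arrays lay in a set without any of the not amplified ones, so set and amplification cannot be separated. Identity was judged by r over the 1000 genes most variable between the 4 not amplified lines, after centring each gene. The amplified arrays labelled PS5 correlated with the not amplified LB2 line at r = 0.769 to 0.782, and those labelled LB2 with PS5 at 0.580 to 0.659. CAV2 and LMS3 arrays matched their own lines (0.519 to 0.658 and 0.627 to 0.680).

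**Figure D4:**
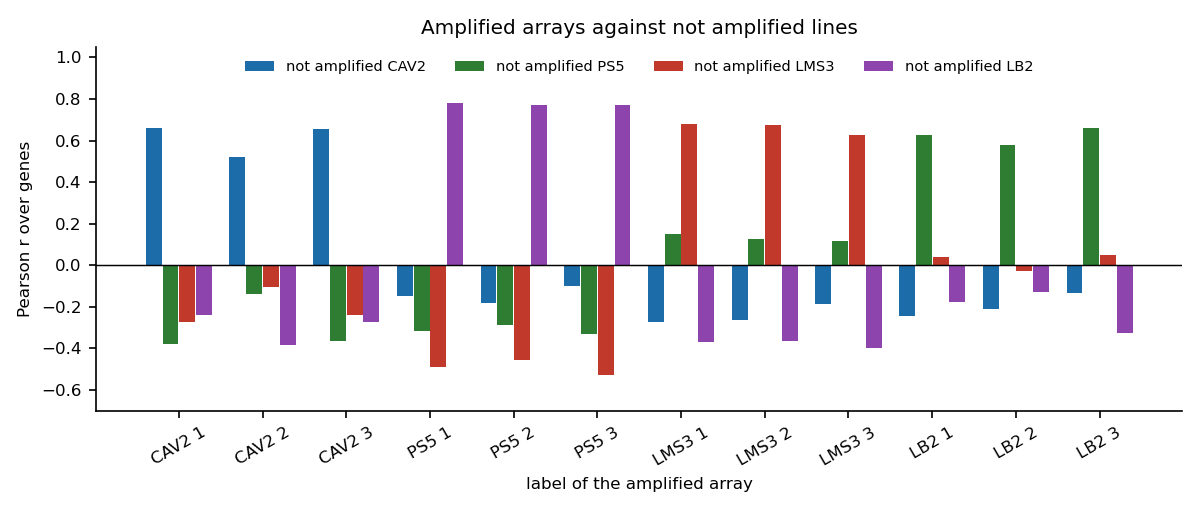
Correlation (r, most variable genes, centred) of each of the 12 amplified EpiSC arrays with the 4 not amplified lines. The arrays labelled PS5 lay highest against LB2 and those labelled LB2 highest against PS5.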

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

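The tests of exchanged labels, of the shared array set and of passage number were chosen only after the results they concern had been seen.

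The amplified arrays labelled PS5 and LB2 each resembled the other line. Distortion by amplification is argued against by the CAV2 and LMS3 arrays, which kept r of at least 0.520 with their own line on autosomal genes. Change in culture is argued against by the Y-linked gene Eif2s3y, which was detected on all 3 arrays labelled LB2 and on 0 of 3 of not amplified LB2, at least 3.03 higher on the log2 scale. An exchange of labels remains the candidate explanation: 6 of 6 arrays correlated best with the other line on autosomal genes. The match does not tell whether the amplified or the not amplified arrays carry the exchanged labels. The tests of stage of origin, distance and stage genes used the not amplified arrays as labelled, and an exchange of these was not tried. No other explanation was tested, biological or technical.

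The arrays labelled iPSC line 3 resembled ESC, with r of 0.995 to 0.996. The shared array set is argued against by iPSC lines 1 and 2, whose highest r with ESC was 0.947. Of 47 genes that separated iPSC lines 1 and 2 from R1-129 cells, 42 (89.4%) were on the ESC side in line 3 and 0 on that of lines 1 and 2. RNA of the ESC line and a hybrid line reprogrammed fully to the ESC state cannot be told apart by this value (89.4% for both), since 43 of the 47 genes are ones that were on in lines 1 and 2 alone, and such genes may differ by strain or by state. Among the ESC arrays themselves r was 0.996, close to that of line 3 with ESC. The Y-linked gene Eif2s3y was not detected in line 3 (4.80) or ESC (4.61), against means of 8.15 and 7.39 in iPSC lines 1 and 2. Both values are what RNA of the ESC line would give, but no test here shows whether a hybrid line could give them.

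Immediate early genes were lower in the CAV2 and CAV3 sublines than in their lines (list means -1.64 and -1.51), and the mean was -0.507 for LMS2 and -0.697 for LB1. For CAV3, whose subline lay in sets 3 and 4, handling of the first array set is argued against by lines CAV4 and PS3, whose culture in that set differed from those of their line in sets 3 and 4 by 0.04 and -0.187 in the list's median. The CAV2 subline lay in set 2, as did those of LMS2 and LB1, and a low level in that set could be part of its change, which these lines do not test. EpiSC9, in set 2 as well, had a list mean of -0.60 against the R1-129 lines (camera adjusted p = 0.0361, adjusted p = 0.708 with an estimated correlation). Passage number is argued against, since the list moved as it requires in only 2 of 4 sublines. Growth state at harvest could still differ between thaws and was not tested.

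The single no bud embryo stood apart from the other bud embryos, with a gap of 0.660 of the range in the primitive streak list, 0.693 in the extraembryonic ectoderm and trophoblast list, 0.695 in the Wnt list and 0.630 in the BMP list. Late streak embryo 3 was far from the others in the imprinted list (0.701), and late bud embryo 1 in the FGF and ERK list (0.678). The Nodal and Activin list set the amplified arrays labelled LB2 apart from the other amplified lines (0.914; 9.56 against 9.25 to 9.28) and LMS2 apart from the other late midstreak lines (0.804; 10.51 against 9.02 to 9.31). In all 8 of 141 such gap tests, on 6 groups of samples, passed, and chance passes about 1 in 20. The change from line to subline differed between LMS2 and the mean of CAV2 and LB1 in 3545 genes by a test of the difference itself, 1825 higher and 1720 lower, with T at -2.79 and Stc1 at 3.72. The array of supplied EpiSC9 RNA detected 15036 probes, outside all comparisons.

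Splits of the samples into groups of the same sizes were counted, the real one included. Only the real split gave as many genes for EpiSC against iPSC (6367 genes, highest other 924, 1 of 100 splits) and between lines (13320, other 84, 1 of 100). The same held for bud against early epiblasts (4089, other 2536, 1 of 100) and amplification (10330, other 4546, 1 of 100). It also held for amplified EpiSC against early (4424, other 93, 1 of 35), streak (3825, other 1744, 1 of 100) and bud epiblasts (5330, other 2982, 1 of 100). These counts make chance less likely, but with at most 100 splits drawn they do not exclude it. Between lines and for amplification single cultures were shuffled, although cultures of 1 line are not independent. Chance cannot be excluded for the stage of origin, where 9 of 100 splits gave at least the 2 genes. One split of the stages called 85 genes, which points to some structure of the lines that no test examined. For late bud against cavity the count was 0 (highest other 0), so 35 of 35 splits had to give as many and decide nothing. With 10 splits a share under 0.05 cannot be reached for the sublines, of which 1 split, the real one, gave 6338 genes for CAV2 (highest other 730), 6428 for CAV3 (41), 5677 for LMS2 (3) and 4829 for LB1 (2).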

How the results depend on the processing

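The alternatives that use array sets, leave out iPSC line 3, leave out or exchange the lines labelled PS5 and LB2, or leave out the 4 embryos with Ttr, and the test of LMS2 against CAV2 and LB1, were chosen after seeing the data. Of 5931 values of 384 single genes under alternatives, 5851 stayed on their side of the threshold, 46 fell short of it, 34 came past it and 0 reversed. The rule for named genes takes the largest fold changes among genes that passed, which seldom change side. These counts therefore do not measure how stable a typical gene is. Of 1006 values of 70 gene lists, 962 stayed, 36 fell short and 8 reversed. All 8 were of lists that did not pass. The mean of naive pluripotency in bud against early epiblasts (-0.08) was 0.28 with a stricter filter, 0.25 without the embryos with Ttr, 0.029 without cavity embryo 1, -0.17 without prestreak embryo 1, -0.040 without the no bud embryo and -0.33 in 1 array set. A reversal means that the direction of camera turned, which it did in all of these but the fit without prestreak embryo 1. For core pluripotency in amplified EpiSC against bud epiblasts the mean of 0.17 was 0.16 without a filter, 0.17 in 1 array set, 0.43 without LMS3 and -0.036 without PS5, with the direction of camera turned in the first 3. Where no cause is given below, the cause was not tested.

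With a 2-fold minimum, which by construction calls fewer genes, 2540 passed against ESC, 2239 against iPSC, 4302 against MEF and 165 for EpiSC9. By the same limit it was 1141 for the CAV2, 1440 for the CAV3, 951 for the LMS2 and 586 for the LB1 subline, 2715 for bud against early epiblasts, 2509 and 3317 for amplified EpiSC against streak and bud epiblasts, and 4366 for amplification. Without a filter 5 genes passed between iPSC and ESC, 949 for EpiSC9 and 20 for the stage of origin. With a stricter one it was 135 for EpiSC9 and 1 for the stage of origin. The stage of origin gave 5 on the deposited values, 10 without sublines, 1 with EB1a and EB1b as 1 line and 5 with the array set as a block. EpiSC9 gave 167 without sublines and 120 in its own array set. Between iPSC and ESC 250 passed with the line as a random block of cultures, 143 with the array set as a random block and 1354 without iPSC line 3. The LMS2 subline less the mean of CAV2 and LB1 gave 3545. Fewer embryos gave 1706 for bud against early and 2495 for amplified EpiSC against early without the embryos with Ttr, and in 1 array set 2270 and 3403 for amplified EpiSC against streak and bud.

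The correlation of similarity with stage (0.0892) became -0.0843 over every probe, -0.125 with rank correlation over genes, 0.798 without the 2 embryos described as cultured, -0.596 without those with Ttr, -0.694 in the array set of late streak, no bud and early bud, and 0.742 without the lines labelled PS5 and LB2. Where embryos or lines were left out, genes were centred again on the rest, so these values do not show the effect of the left-out samples alone. The value for the own stage of origin was -0.122 with these labels exchanged.

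Leaving out 1 replicate at a time in groups of 2 to 5 gave 3963 to 4010 genes against ESC, 4860 to 5143 against iPSC, 6728 to 6881 against MEF. It was 0 to 1354 for iPSC against ESC, 183 to 611 for EpiSC9 (611 without culture 1), 0 to 3 for the stage of origin (0 without EB1b, 1 without EB1a), 0 for late bud against cavity and 11750 to 12747 between lines. Sublines gave 5397 to 5974, 5635 to 5949, 4684 to 5019 and 3809 to 4247 for CAV2, CAV3, LMS2 and LB1. Epiblasts gave 3102 to 3861 for bud against early, 3645 to 4482, 2826 to 4017 and 4298 to 5427 for amplified EpiSC against early, streak and bud epiblasts, and 9210 to 10192 for amplification. Similarity, with genes centred again in each fit, ran from -0.368 (without LMS3) to 0.646 (without PS5). Own stage ran from -0.154 to 0.00173, the distance from -0.00684 to -0.00467 and the stage genes from -0.306 to -0.0765.

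Culture numbers were not used as pairs: residuals of cultures with 1 number had a median r of 0.002 over the EpiSC lines and -0.0151 over ESC and iPSC. Over the EpiSC lines 176 of 672 such pairs were over 0.1 and the highest was 0.696, so a median near 0 does not exclude shared structure. Over ESC and iPSC 3 of 18 pairs were over 0.1 and the highest was 0.867. The cultures numbered 1 of iPSC lines 1 and 2 had r = 0.995 with each other and at most 0.967 with their own lines. With the line number as a replicate block 0 genes passed for the stage of origin, and with the replicate block on top of the line 247 for iPSC against ESC. Median scaling moved the median log2 fold change of all genes from 0.11 to -0.13 against MEF, from -0.03 to 0.12 for LB1 and from 0.14 to -0.10 for amplification. Folds of genes near the floor are limited by signal over background: where only some arrays of the dimmer group detected a gene and no bound was set, its fold is uncertain in size. A block of slides was not run, since the files name none.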

Other observations

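The test of anterior streak against neuroectoderm genes was chosen only after the results had been seen.

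The array of supplied EpiSC9 RNA had r across genes of 0.956 to 0.968 with the EpiSC9 cultures, 0.881 to 0.959 with R1-129 EpiSC and 0.818 with MEF. The ranges for EpiSC9 and R1-129 overlap; within its own array set r with R1-129 EpiSC was 0.941 to 0.949. Nr5a2, high in EpiSC9, was at 9.80, and the naive gene Dppa5a at 9.18. Egr2, a gene of the immediate early response, was at 9.51 in the supplied RNA and 5.48 in the EpiSC9 cultures.

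Sex chromosome genes set the lines apart. Eif2s3y was not detected in ESC (4.61) or in the arrays labelled iPSC line 3 (4.80), while iPSC line 1 had 8.15 and iPSC line 2 had 7.39.

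A hypothesis was that lines high in anterior streak genes are low in neuroectoderm genes. The values argue against it: over the 18 line means Pearson r was 0.462 (permutation p = 0.0518) and Spearman rho 0.265 (permutation p = 0.288), 2-sided, which is the opposite direction. Without LMS1 and LB2, the 2 lines farthest from the median, r was 0.0261, so the value rests on those lines. Within array set 1 (6 lines) r was 0.238 (exact p = 0.722), and within sets 3 and 4 (10 lines) 0.366 (permutation p = 0.303).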
